A study of Rattus norvegicus with 6 samples.

How the data were processed

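Polyadenylated RNA from the superficial superior colliculus of Sprague Dawley rats was analysed in 6 libraries, 3 with eyelids glued closed and 3 with eyes open, each from 1 of 3 labelled batches. Tissue was kept in a stabilising solution, and RNA was extracted with a phenol-based reagent and column cleanup, per the labels' protocols. The submitters' processing notes name STAR, featureCounts 1.4.4, Cufflinks 2.1.1, DESeq2 1.4.1 and the genome build rn5. Which tool made which column, the gene annotation and the filters are not given in the sources used here.

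The authors deposited FPKM values (fragments scaled by transcript length and by library size) for 26402 Ensembl gene IDs and the 6 libraries, per the labels. FPKM divides by transcript length and library total, so a value for an ID with few reads can be large and imprecise. Low FPKM values were searched for steps of 1 read: between the 15 pairs of libraries, the commonest 0.5% ratio bin held 0.888% to 3.65% of IDs with a mean under 0.05 FPKM, so no depth was recovered and no interval for counting error is given. The authors also deposited 1 table of their own comparison, made with DESeq2 per the labels. It holds a signal value per ID on the scale of a mean normalized count, a log2 fold, and a p-value and adjusted p-value. That the signal column is the mean normalized count was taken from its scale: the 6056 IDs without a p-value are all at 0. The deposited log2 fold is open over closed, as its sign against FPKM showed, and it was turned to closed over open here. The folds are small in range. The 70 IDs with an FPKM fold of at least 2 had a median deposited log2 fold of only 0.0148 in size, as shrunken folds would have. Whether the deposited folds were shrunken, and whether the authors' model had a batch term, is not given in the sources used here. No raw counts per library were used, so no count model was fitted.

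The tables carry Ensembl gene IDs without symbols, and the reference table at hand, of 47357 rows, holds 0 Ensembl IDs. The 35 planned gene lists therefore could not be matched, and no list, pathway or cell type was tested. Coordinates were not used here. The rule for singling out IDs took those called by the authors' table with the same direction in all 3 batches, by size of the deposited fold, because limma made no call without the block. With no symbols it was limited to 2 IDs per direction. Only 1 ID that fell met it, and the 1 ID called with the block, chosen after its values were seen, took the remaining place. The rule as planned allowed more IDs and would have filled open places from the smallest unadjusted p without the block. That step was not used.

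The test, the filter, the threshold, the gene lists and the rule for named IDs as planned were set before the data were examined. The comparison used limma 3.58.1 in R 4.3.3, with statmod 1.5.0, on log2(FPKM + 0.5), for IDs with a mean of at least 1 FPKM over all 6 libraries, with trend and robust variance moderation, two-sided p and Benjamini-Hochberg adjustment at 0.05. Folds are on this log2 scale and understate changes of low IDs. The batch letter is a label shared by the groups, so it pairs the libraries. After removal of group means, closed and open libraries of one batch correlated at 0.361 to 0.525. Those of different batches correlated at -0.375 to -0.0508, but negative values there follow in part from the positive ones, since deviations within a group cancel out. Because libraries of one batch were alike, the fit with batch as a replicate block is given beside the main one wherever it moves a count. Measures per library were compared with exact permutation tests, unpaired and paired by batch.

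The fits were tested on simulated data with the real means and batch offsets of 12351 IDs and 200 changed IDs in each of 10 runs. Noise was normal, with variances drawn from the blocked fit, and the eye difference did not vary between batches. The blocked model thus held by construction, and its results there are a best case. Without the block, 1.04% of IDs changed 1.5-fold, 58.1% of those changed 2-fold and 97.9% of those changed 4-fold were recovered. With the block these were 86%, 99.6% and 99.8%. The average share of false calls among all calls was 0.0917% without and 6.28% with the block. Alternatives were other pseudocounts (0.1 and 1), other filters (a mean above 0 or of at least 5 FPKM), quantile, upper-quartile and median scaling, plain variance moderation, and each library or batch left out.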

Results

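RNA was profiled in the superficial layers of the superior colliculus, the midbrain layers that receive input from the retina, in Sprague Dawley rats at postnatal day 20. In 3 libraries the eyelids had been kept shut with glue from postnatal day 14 to day 20, and in the other 3 libraries the eyes were open over the same days. Each group held 1 library from each of the batches A, B and C. The comparison asks which transcripts differ in abundance when the eyes are kept from opening. The polyadenylated RNA was read out as FPKM for 26402 Ensembl gene IDs, and the authors also deposited their own comparison of the groups for 26403 IDs. The tables give IDs without gene symbols, so genes are named here by ID, without function or position, and only 4 IDs are singled out.

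Sequencing depth per library is unknown, because FPKM does not keep it. The authors' mean normalized counts summed to 18809923 over all IDs, which describes an average library. Between 12141 and 12458 IDs reached 1 FPKM in a library, with 12268 ± 116.3 in the closed group and 12333 ± 155.4 in the open group (SD, n = 3 each, exact two-sided permutation p = 0.5). The closed library had fewer such IDs than the open library in all 3 batches (exact paired permutation p = 0.25, two-sided, the smallest that 3 pairs allow). The 10 most abundant IDs took 29.04% ± 0.4618 of summed FPKM in closed and 27.18% ± 2.736 in open libraries (SD, n = 3 each, exact two-sided permutation p = 0.4), and this share was higher in closed in 2 of 3 batches (exact paired permutation p = 0.5). Without pairing, 3 libraries against 3 allow no p under 0.1.

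The libraries were ordered by batch and not by eye condition. Across 12351 IDs with a mean of at least 1 FPKM, batch took 66.9% of the sum of squares of the log2 values, eye condition 11.9% and the remainder 21.2%, where 40%, 20% and 40% follow from the degrees of freedom alone. Per degree of freedom, eye condition therefore took about as much as the remainder. Closed and open libraries of one batch correlated across IDs at 0.9819 to 0.9837, and libraries of one group from different batches at 0.9653 to 0.9798. With batch and eye condition in 1 limma fit, 6138 of the 12351 IDs differed between batches at an adjusted p under 0.05.

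**Figure D1:**
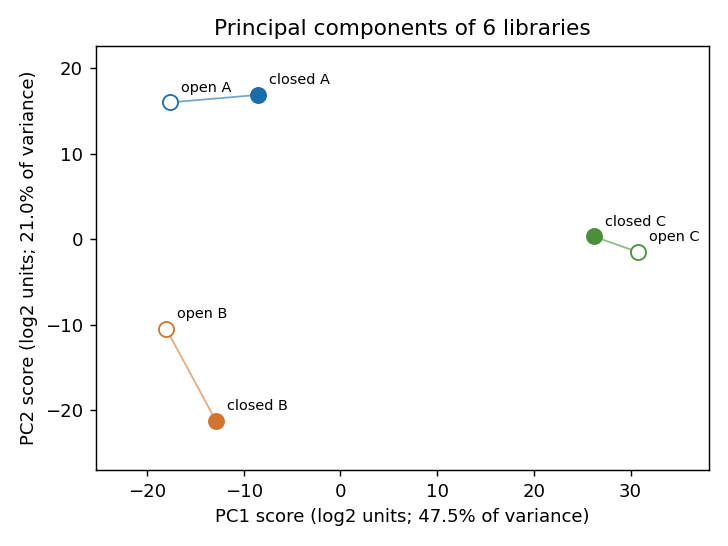
Scores of the 6 libraries on the first and second principal component of log2(FPKM + 0.5), in log2 units, with filled points for closed eyes, open points for open eyes and a line joining the libraries of one batch. The first component (47.5% of variance) sets batch C apart at 26.2 and 30.7, and the second (21.0%) separates batch A from batch B, while closed and open libraries of a batch lie next to each other.

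No ID passed the test between closed and open eyes when the 6 libraries were compared without regard to batch. None of the 12351 IDs passed an adjusted p under 0.05 in limma, and 67 IDs (0.542%) had an unadjusted p under 0.05, of which 12 were higher and 55 lower in closed eyes. With the batch, a label shared by both groups, as a block, 1 ID passed, and 780 IDs (6.32%) had an unadjusted p under 0.05, where uniform p-values would give 5%. Other groupings that part every batch pair but mix closed and open eyes gave 244, 1307 and 332 such IDs. The 780 thus lie within the range of groupings without the eye contrast. Of these 780 IDs, 247 were higher and 533 lower in closed eyes as deposited, but 441 were higher and 336 lower among 777 IDs after each library was set to the same median, so the predominance of lower IDs depends on the scaling. Leaving out single libraries from the comparison without block gave 2 calls without closed A, 3 without closed B, 3 without open B, 2 without open C, and none without closed C or open A. The number at an unadjusted p under 0.05 was 347 without open C and 120 without closed C. The p-values measure the spread between these samples, since the labels do not say how many animals went into each library.

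The difference between closed and open eyes was bounded more narrowly with the block than without it. With the block, the 95% interval of the fold lay inside 1.5-fold in either direction for 11937 IDs (96.6%), and without it for 10255 IDs (83%). The median half-width of the interval was 1.13-fold with the block and 1.28-fold without. Without the block, 6162 IDs were bounded within 1.5-fold when batch A was left out, 5614 without batch B and 10498 without batch C, and with the block 11641, 11725 and 11489. The share of IDs bounded within 1.5-fold with the block was 95% among the 6696 IDs with a mean of 1 to 10 FPKM, 98.7% among the 5258 IDs at 10 to 100 FPKM and 98% among the 397 IDs at 100 FPKM or more. Without the block these shares were 81.5%, 86.2% and 66.5%. These intervals are per ID and not adjusted for the number of IDs.

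The closed-minus-open difference was weakly shared, by rank, between batches A and B and not clearly shared with batch C. Its correlation across IDs, which are not independent replicates, was 0.0537 (Pearson) and 0.221 (Spearman) between batches A and B, 0.00344 and -0.0546 between A and C, and 0.0549 and 0.00927 between B and C. All 3 batches moved the same way for 1038 IDs that were higher in closed eyes and 2411 that were lower, together 27.9% of IDs where chance gives 25%. After each batch's difference was centred on its median, 1725 IDs were higher and 1688 lower in all 3 batches. The share with one direction was 29% among IDs at 1 to 10 FPKM, 26.9% at 10 to 100 FPKM and 23.4% at 100 FPKM or more.

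**Figure D2:**
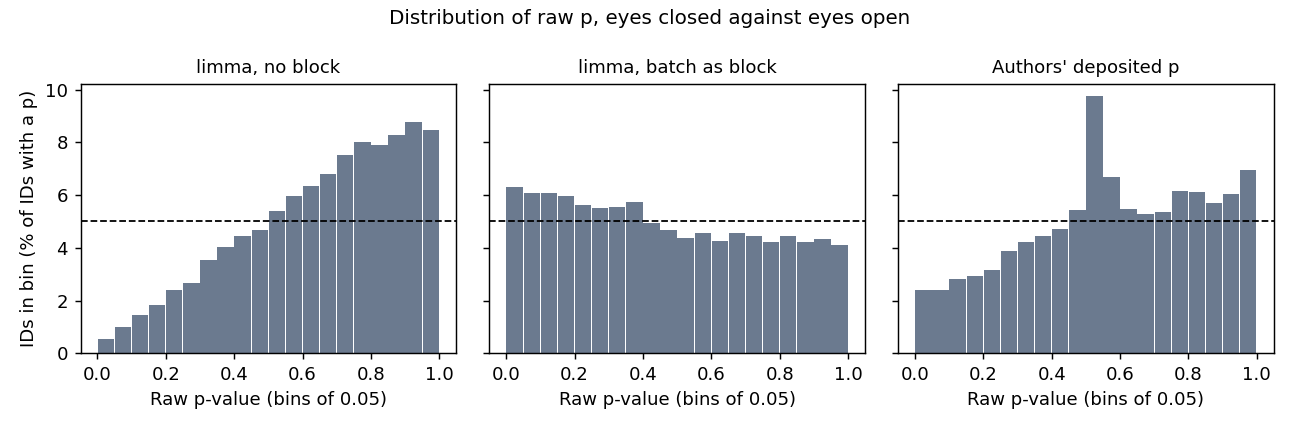
Distribution of unadjusted p-values for closed against open eyes, as the percentage of IDs in each bin of 0.05, for limma without block, limma with the batch as a block and the authors' deposited table, with a dashed line at the 5% that uniform p-values would give. The lowest bin holds 0.542%, 6.32% and 2.40% of IDs.

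The authors' own comparison called 7 of 20347 IDs with a p-value, 6 higher in closed eyes and 1 lower. In the authors' deposited table the same 7 IDs passed adjusted p thresholds of 0.05 and 0.1, and 489 IDs (2.4%) had an unadjusted p under 0.05. Of those 489, the deposited folds of 322 were higher in closed eyes and of 167 lower, and of 313 and 148 among IDs with a mean of at least 1 FPKM. FPKM as deposited leaned the other way in the fit with the block (247 higher and 533 lower). After median scaling it leaned the same way (441 and 336). The deposited log2 folds are small, none above 0.551 in size, and are quoted here with their sign turned to closed over open. In FPKM, 4 of the 7 IDs could be followed, and each lay in its deposited direction in all 3 batches. This is no separate evidence, since both tables come from the same libraries and the orientation of the deposited fold was itself read from FPKM. The remaining 3, all higher in closed eyes in the authors' deposited table, were listed at 0 FPKM in every library although their deposited mean normalized counts were 151.8, 97320 and 35.88. Their FPKM says nothing about their level.

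ENSRNOG00000029042 had the largest deposited difference, a log2 fold of 0.55 with an adjusted p of 5.47e-13 in the authors' deposited table. Its abundance was 3067 ± 600 FPKM in closed and 2290 ± 548 FPKM in open eyes (SD, n = 3 each). The closed library was above the open library in each batch, by 0.485, 0.349 and 0.457 on the log2(FPKM + 0.5) scale in batches A, B and C. The limma log2 fold was 0.43 (SE 0.24, adjusted p = 1) without the block and had an SE of 0.0745 with it (adjusted p = 0.427). Without the open library of batch C the log2 fold was 0.27.

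ENSRNOG00000033299, also higher in closed eyes in the authors' deposited table, had a log2 fold of 0.53 there with an adjusted p of 1.17e-08. Its FPKM was 7945 ± 3270 in closed and 5395 ± 1420 in open eyes (SD, n = 3 each). The batches differed in size for this ID, with log2 differences of 0.639 in A, 0.12 in B and 0.80 in C. The limma log2 fold was 0.52 (SE 0.32, adjusted p = 1), with a blocked adjusted p of 0.664, and fell to 0.20 without the closed library of batch C. It was 0.31 without the open library of batch A and 0.29 with quantile scaling of all libraries.

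ENSRNOG00000011292 was the single ID called lower in closed eyes in the authors' deposited table, with a log2 fold of -0.36 and an adjusted p of 0.00408. It stood at 12.16 ± 2.72 FPKM in closed and 16.84 ± 3.21 FPKM in open eyes (SD, n = 3 each), and the log2 differences of closed from open were -0.34, -0.63 and -0.41 in batches A, B and C. The limma log2 fold was -0.46 (SE 0.19, adjusted p = 1), and the blocked adjusted p was 0.427.

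ENSRNOG00000047360, chosen after its values were seen, was the 1 ID called by limma with the block, where it fell in closed eyes (log2 fold -1.84, blocked SE 0.16, adjusted p = 0.0465). Its FPKM in batches A, B and C was 4.63, 4.76 and 1.90 with open eyes and 0.893, 1.53 and 0 with closed eyes. The authors' deposited table gave this ID a mean normalized count of only 3.449, a log2 fold of -0.00501 and an adjusted p of 1. Deposited folds near 0 were usual for such IDs: the 70 IDs with an FPKM fold of at least 2 had a median of 0.0148 in size. Shrunken folds and counts without a difference would both give this. The deposited values thus show no difference for this ID, and whether they speak against one cannot be told. The call was lost when the pseudocount was 0.1 (log2 fold -2.72, adjusted p = 0.775) and when the libraries were set to the same median (log2 fold -1.81, adjusted p = 0.331), while the fold stayed of like size or larger. Its adjusted p ranged from 0.000414 to 1 over 27 alternative settings.

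**Figure D3:**
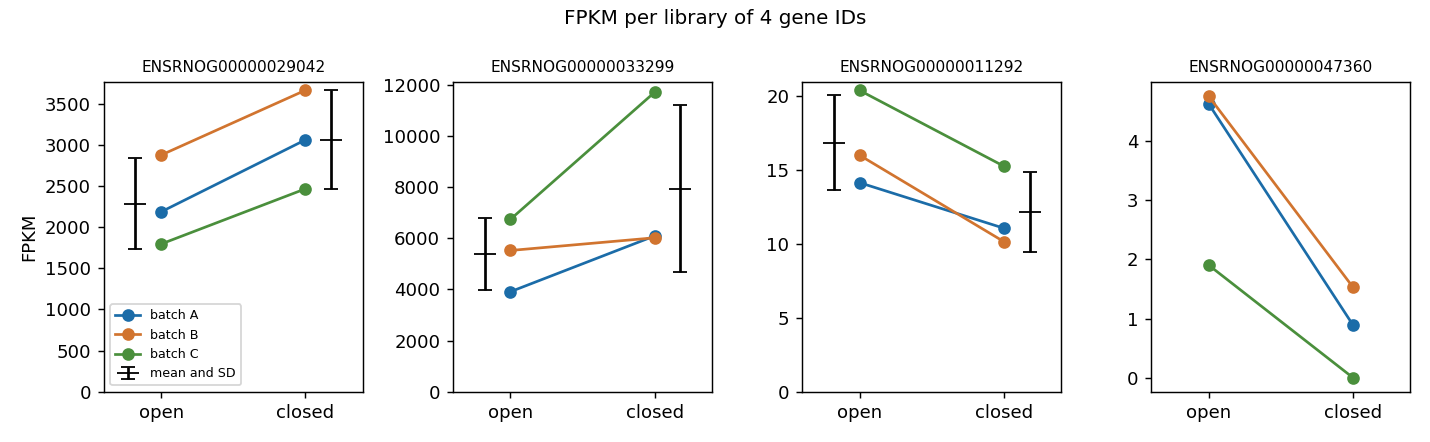
FPKM of 4 gene IDs in each library, from open to closed eyes, with one line per batch and, where no library was at 0, the mean and SD of 3 libraries beside each group. ENSRNOG00000029042 and ENSRNOG00000033299 were higher and ENSRNOG00000011292 and ENSRNOG00000047360 lower in the closed library of every batch.

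Over all 12344 IDs with values in both tables, the FPKM folds and the deposited folds correlated at 0.433 (Pearson) and 0.75 (Spearman) across IDs. Among the 11147 IDs with a deposited mean normalized count of at least 100, these were 0.69 and 0.765. Both tables come from the same libraries, so this compares the tables and is not a second measurement.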

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

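Median scaling, the added filter on the deposited mean normalized count of at least 10 and every combination of the block with another setting were chosen after seeing the data; the other settings were planned. Without the block, 12 of 19 settings gave 0 calls in limma. Leaving out 1 library gave 0 to 3 calls, and leaving out batch A, B or C gave 3, 5 and 3. With the replicate block, the paired fit gave 1 call, ENSRNOG00000047360. It gave 1 call with a pseudocount of 1, that ID again, 1 call with a pseudocount of 0.1, another ID, and 0 calls in the other filters, scalings and plain moderation. The filters at a mean of at least 5 FPKM and at a mean normalized count of at least 10 removed ENSRNOG00000047360 before testing, so their 0 calls say nothing about it. The paired fit without batch A, B or C gave 6, 16 and 2 calls; fewer samples were fitted there, and the cause was otherwise not tested. IDs at an unadjusted p under 0.05 numbered 24 to 363 without and 447 to 1622 with the block, and IDs with an interval inside 1.5-fold 5614 to 15952 and 8278 to 18277, in part because the filters tested other numbers of IDs. Added to the planned fit, the block changed no call but that of ENSRNOG00000047360. The folds of ENSRNOG00000029042, ENSRNOG00000033299 and ENSRNOG00000011292 kept their direction in all 31 settings and were called in none. ENSRNOG00000047360 kept its direction in the 27 settings that tested it and was called in 3, all with the block. The 7 deposited calls stayed 7 at an adjusted p of 0.1 and became 4 among IDs with a mean of at least 1 FPKM, since 3 are listed at 0 FPKM. The planned gene list tests and list scores were not run, because the IDs could not be matched to symbols, and count models were not run, because no reads were recovered. In simulated data, changes of 1.5-fold were mostly missed without the block.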

Other observations

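Of the tests below, those on variance moderation and on the sign of the count-based folds were set before their results were seen, and all others after. For the sign of the folds, the criterion set beforehand, an exact interval above 50%, was met, but it was dropped after the value was seen: noise shared by tables from the same libraries gives a like sign without any difference between the groups. The limit of 10 counts per FPKM was also chosen after the ratios of the deposited calls had been seen, and 3 of those calls are among the IDs it selects. The numbers of most abundant IDs looked at, 20 and 200, were chosen after a first look at 50. Gene names were not matched, so no biological function was examined, and an effect of eyelid closure stays open as an untested explanation for each pattern.

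The splits of the 6 libraries are too few to reach a share under 0.05. In limma, the real split into closed and open gave 0 calls, and the highest other split gave 3. All 10 splits of 3 against 3 gave at least as many as the real one, which 0 calls made certain beforehand. IDs at an unadjusted p under 0.05 numbered 67 in the real split, against 49, 30 and 29 in the other splits with 1 library of each batch on each side. So few splits allow no test of whether 67 is high. In the paired fit, the real grouping gave 1 call and 780 IDs at an unadjusted p under 0.05. All 4 splits that part every batch gave at least 1 call, the highest other 6 calls. Their other counts at an unadjusted p under 0.05 were 244, 332 and 1307. In the unpaired splits that count reached 3189 for the split that sets closed A, open A and open B against closed B, closed C and open C, and 2887 for the one that sets both batch C libraries with closed A. These point to a structure of the samples by batch.

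Small p-values were rarer than the 5% of a uniform distribution without the block (0.542% of IDs under 0.05, where simulated unchanged IDs with the real batch offsets gave 0.246%) and in the authors' deposited table (2.4% of 20347 IDs, and 3.73% of the 12344 IDs with a mean of at least 1 FPKM). Moderation of the variances is argued against as the cause, since ordinary variances per ID still left 1.43%. For the fit without the block, a candidate explanation is variation between batches left in the residual: with the batch as a block the share was 6.32%, and 5.06% of simulated unchanged IDs. In the authors' deposited table the shortage lay mostly among IDs with few counts, with an unadjusted p under 0.05 for 0.0175% of 5723 IDs under a mean normalized count of 10, 0.958% of 3340 IDs at 10 to 100 and 4.04% of 11284 IDs at 100 or more. Whether its test had a batch term cannot be told apart: its p ranked slightly closer to the blocked p than to the unblocked p (difference of rank correlations -0.0268 across 11147 IDs), but it also ranked almost exactly by the size of the deposited fold (rank correlation -0.995), so the comparison reads fold size and not the model.

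The largest FPKM folds sat on IDs with few reads. Of the 12351 IDs, 70 had a fold of at least 2 (34 higher and 36 lower in closed eyes), and their median deposited mean normalized count was 6.29 (quartiles 2.13 and 17.6), against 572 for all tested IDs. Imprecise length-normalised values of IDs with few reads may therefore explain these folds, including that of ENSRNOG00000047360. Of the 70, 1 had a deposited p under 0.05. This is no evidence against a difference, since few IDs at such counts reached it: 0.0175% under a mean normalized count of 10 and 0.958% at 10 to 100. A real difference in read counts cannot be told apart, since the deposited fold had the same sign in 64.3% (exact 95% interval 51.9% to 75.4%) but both tables come from the same libraries.

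The deposited calls higher in closed eyes with FPKM above 0 lay among abundant IDs with few counts per unit of FPKM. A shift of the 200 most abundant IDs, which hold 4 of the 7 deposited calls, is argued against, since 88 leaned higher in closed eyes (44%, exact 95% interval 37% to 51.2%), as did 26 of the top 50 (37.4% to 66.3%), but for the 1 call among the top 20 such a shift cannot be told apart, since 14 of the other 19 leaned higher (73.7%, 48.8% to 90.9%). Among IDs with a mean normalized count of at least 1000, 17 of the 21 with fewer than 10 counts per FPKM leaned higher (81%, 58.1% to 94.6%), and 14 of 18 without the deposited calls (77.8%), against 50.1% of the other 4114, though the intervals take IDs as independent. A shift of this class is a candidate explanation. In FPKM, 12, 11 and 16 of the 21 IDs were higher in closed eyes in batches A, B and C, or 14, 13 and 15 relative to the median of all tested IDs. Their share of summed FPKM was 6.07% ± 1.23 in closed and 4.95% ± 0.588 in open libraries (SD, n = 3 each, exact permutation p = 0.3). The share was higher in closed in all 3 batches (exact paired permutation p = 0.25, the smallest that 3 pairs allow). These counts and shares include the 3 deposited calls, each higher in closed eyes in every batch. They are thus partly drawn from the calls to be explained, and were not computed without them. Whether eyelid closure or library preparation lies behind such a shift stays open.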
